A study of Homo sapiens with 94 samples.

How the data were processed

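Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in HCT116, a human colorectal cancer cell line, after 6 h in tunicamycin at 0.5 µg/ml or in 0.1% DMSO as vehicle. Per the labels' protocols, cells were fixed with formaldehyde, the chromatin was sonicated and immunoprecipitated, and sequencing adapters were inserted by tagmentation while the chromatin was still on the beads. The series holds 94 samples. Peak lists of 92 libraries were used, and the 2 input libraries, which come without a peak list here, entered no comparison. Groups were taken from the sample titles, which give the antibody, genotype, treatment, replicate number and, for H3K27ac, a SET number from 1 to 5 whose meaning is not given in the sources used here. The 92 libraries form 46 groups of 2 replicates. The series text calls the replicates biological but does not say whether they came from separate cultures. The p-values of tests over libraries therefore measure the spread between these libraries. Those of tests over regions or sites do not measure that spread.

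Each file is a list of peaks called in a single library, without pooling of replicates. Trim Galore, BWA 0.7.17, SAMtools, Picard 2.18.23 and MACS2 2.2.7.1 and the build hg19 are named in the submitters' processing notes, which give neither their roles nor their order, and whether the input was used in peak calling is not given in the sources used here. The deposited lists are in the narrow peak layout of MACS, where the fold enrichment of each peak is a ratio to the background as the authors' peak caller computed it, and the deposited significance columns hold −log10 of the p-value and of the q-value. These per-peak values are the authors' own and served only to describe, rank or filter peaks within a list. The peak names in 56 of the lists carry a q threshold of 0.05, and the smallest −log10 q over the deposited lists was 1.30. The running numbers in the deposited peak names skip between 1.16% and 1.72% of the peaks in the H3K27ac lists and up to 96.1% in a CHOP list, so the lists used here may not hold every called peak. Only autosomes and the X chromosome occur, 23 chromosomes in all. The lists hold no read counts. Depth per library is therefore unknown, and a missing peak can mean a weak signal or a shallow library.

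Peaks of all libraries of an antibody were merged into regions wherever they overlapped by at least 1 bp, and regions with a peak in at least 2 libraries were kept. A library was scored as having a peak in a region when a peak overlapped it by at least 1 bp. This gave 50748 H3K27ac regions and 32833 ATF4 regions. Scoring presence or absence keeps the comparison free of the peak heights, whose scale can differ between libraries, but a region whose signal rises from moderate to high is then not seen as changed.

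Treatments were compared per region with Fisher's exact test, two-sided, on the number of libraries with a peak, with Benjamini-Hochberg adjustment over testable regions and a threshold of 0.05. A region was testable when its number of libraries with a peak allowed an unadjusted p under 0.05, which was 5 to 15 of 20 libraries for wild-type H3K27ac and 5 to 19 of 24 libraries for the knockouts and for ATF4. Regions past the threshold were called gained when more tunicamycin libraries had a peak and lost in the opposite case. Peak numbers were compared on the log2 scale with permutation tests of 100000 resamples, or with exact permutation tests where a group had fewer than 10 libraries. Differences in ATF4 peak number between genotypes were tested by an exact permutation test, one-sided, over every way to pair the 12 libraries of a treatment. Groups of 2 against 2 libraries cannot give an exact two-sided p below 0.333, so single knockouts are described by values and spread.

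For each knockout, gained regions were chosen from the 16 wild-type libraries of the other 4 SETs only, so that the libraries compared did not choose them. The choice was still made in wild-type cells, which can favour wild type in the comparison. Control regions were testable regions with an unadjusted p of 0.5 or more, weighted to the same number of libraries with a peak. A permutation test with 100000 resamples of the genotype labels within SETs covered the 6 knockouts together. Factor peaks were counted at a region when both wild-type tunicamycin libraries of the factor had a peak there. Their enrichment was tested with Fisher's exact test over regions against the testable regions that were not gained, and regions are not independent replicates. Co-occurrence of factors was tested over H3K27ac regions with a peak in at least 5 of the 10 wild-type tunicamycin libraries. Odds ratios are given with exact 95% intervals.

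The named regions are, for each treatment test, the 10 gained and 5 lost regions with the smallest p. Ties were ordered by the difference in library number, by the mean within-list percentile of the −log10 q and by position. For single factors they are the 5 tunicamycin-only sites with the highest mean percentile. Coordinates are 1-based positions on hg19. The gene table at hand belongs to GRCh38.p14, another build, so regions are named by position alone. The gene lists fixed in advance and the loci of the 6 factors are not analysed here, and the knockouts were not checked at the targeted genes. The groups, the main tests, the alternatives and the naming rule were fixed before the data were examined. The comparison of calls between wild type and knockouts, the counts of factor combinations and of factor peaks in DMSO or at lost regions, the share of factor sites with an ATF4 peak by site class, and the gained regions of the other SETs looked up in the SET left out were added afterwards.

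Libraries with the same SET and replicate number, or the same genotype and number, were checked for pairing across treatments. In H3K27ac the deviations from the treatment means correlated at 0.110 to 0.409 in wild type and 0.211 to 0.397 in the knockouts. The deviations from the mean of their own SET or genotype correlated at -0.0108 to 0.123 and -0.0345 to 0.0271, so the shared part lay between SETs or genotypes more than between replicate numbers. Tests with the pairs as blocks were run as alternatives. Other alternatives were a −log10 q of at least 5, lists of equal length, peaks that cover at least 50% of the region, merging within 500 bp, testing of every region, tests stratified by SET or genotype, and leaving out each library, SET or genotype. A background of all H3K27ac regions with a peak in at least 5 of the 10 wild-type tunicamycin libraries, in place of the testable ones, was added for the factors at gained regions after the data were seen.

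Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Merging and overlap were checked against bedtools 2.31.1. The region tests were tested on simulated data in which some regions went from a peak in few libraries to a peak in nearly all. The tests recovered part of the regions with that large change and fewer of those with a smaller one. Fewer regions were changed in the simulation than were called as gained in the data, which makes the adjustment stricter. Its recovery therefore does not carry over to the data, where regions that respond in a part of the libraries may be missed. No 2 lists held the same peaks.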

Results

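The data comprised 92 peak lists from HCT116 cells, a human colorectal cancer line, exposed for 6 h to DMSO or to tunicamycin, an inhibitor of N-linked glycosylation that causes endoplasmic reticulum (ER) stress. H3K27ac, a histone acetylation mark of active promoters and enhancers, was measured in 44 libraries. Of these, 20 came from wild-type cells in 5 SETs and 24 from cells lacking 1 of 6 transcription factors. The ATF4, ATF6 and XBP1 knockouts belong to SET 2 and share its wild-type libraries, and the CHOP, CEBPB and NFIL3 knockouts belong to SETs 3, 4 and 5. ATF4, a transcription factor of the integrated stress response, was measured in 24 libraries of wild-type cells and 5 knockouts. CHOP, a stress-induced factor encoded by DDIT3, was measured in 8 libraries of wild-type and ATF4 knockout cells. CEBPB, NFIL3, ATF6 and XBP1 were measured in 4 wild-type libraries each. Every group had 2 replicates. The H3K27ac lists held 28466 to 43124 peaks, and 74.7% to 89.6% of the peaks of a replicate overlapped a peak of its partner. Read depth is unknown.

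The first comparison asked which H3K27ac regions responded to tunicamycin in wild-type cells. Of 11277 testable regions, 2840 gained the mark and 260 lost it (Fisher's exact test, n = 10 libraries per treatment, adjusted p under the threshold of 0.05). A peak in 10 of 10 tunicamycin and 0 of 10 DMSO libraries was seen at 987 gained regions, and the opposite at 7 lost regions. Gained regions had a median width of 1443 bp and lost regions of 1189 bp, against 1080 bp for testable regions. The 10 leading gained regions lay on chromosome 2 at 53784303 to 53789761, 135881225 to 135886499 and 71604797 to 71607433, on chromosome 12 at 27854196 to 27858831 and 93621529 to 93625038, on chromosome 11 at 15073135 to 15080196 and 61714836 to 61720083, on chromosome 1 at 87244342 to 87248303 and 65412445 to 65417311, and on chromosome 4 at 38169952 to 38173048. Each had a peak in 10 of 10 tunicamycin libraries and 0 of 10 DMSO libraries (Fisher's exact p = 1.08e-05, adjusted p = 0.000123), and each carried ATF4, CHOP and CEBPB peaks in wild-type tunicamycin cells. The 5 leading lost regions lay on chromosome 3 at 32267657 to 32269820, on chromosome 6 at 78005646 to 78006823 and 8958429 to 8959237, on chromosome 21 at 32897853 to 32899383, and on chromosome 11 at 10699318 to 10701568. They had a peak in 0 of 10 tunicamycin and 10 of 10 DMSO libraries with the same p, and carried none of the 6 factors.

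For each SET, gained regions were also chosen from the other 4 SETs alone, 2215 to 2342 regions. Between 85.4% and 92.1% of them had more tunicamycin than DMSO libraries with a peak in the SET left out, and 2 to 5 had fewer. Over all regions, those with a peak in both tunicamycin and neither DMSO library of a SET numbered 2983 to 4181, against 549 to 1373 with the opposite pattern. The number of H3K27ac peaks was 35001 ± 3875 (SD, n = 10) in DMSO and 38428 ± 2848 (SD, n = 10) in tunicamycin, a log2 ratio of 0.14 (permutation test, two-sided, p = 0.0331). The log2 ratio ranged from 0.04 to 0.31 over the 5 SETs. Without either DMSO library of SET 2 or SET 3, either tunicamycin library of SET 1, or tunicamycin replicate 2 of SET 3, the permutation p of the peak number lay between 0.0559 and 0.0650 (n of 9 and 10). The number of gained regions was 1820 at the stricter peak threshold and 1953, with 349 lost, when all lists were trimmed to equal length, and that of lost regions moved between 70 and 497 over the alternatives.

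The same question was asked of the knockout cells, with no wild-type library in the test. Of 12671 testable regions, 1420 gained H3K27ac with tunicamycin and 75 lost it (Fisher's exact test, n = 12 libraries per treatment). Among the 7342 regions testable in both tests, 1136 were gained in wild type and in knockouts, where 352 would be shared by independent lists (odds ratio 49.3, 95% interval 40.6 to 60.3), and 27 were lost in both, where 1.23 would be shared. Only 5 gained regions had a peak in 12 of 12 tunicamycin and 0 of 12 DMSO libraries (Fisher's exact p = 7.4e-07, adjusted p = 0.00134). They lay on chromosome 12 at 88211932 to 88217802, on chromosome 1 at 66277052 to 66279501 and 15616252 to 15617706, on chromosome 8 at 124179385 to 124180257, and on chromosome 4 at 157214782 to 157215997. The next 5, with 11 of 12 against 0 of 12 libraries, lay on chromosome 8 at 123650865 to 123654563, on chromosome 7 at 94451697 to 94456381, on chromosome 4 at 123793130 to 123796547, on chromosome 14 at 40777692 to 40783477 and on chromosome 2 at 23702471 to 23704654. The leading lost regions lay on chromosome 17 at 59638131 to 59640377, 44859766 to 44860665 and 59630014 to 59632106, on chromosome 19 at 18313620 to 18314854, and on chromosome 10 at 72356715 to 72357730. With the genotype and replicate pairs as blocks, 2322 regions were gained and 209 lost, and the main 1420 and 75 were all among them, while 842 and 24 were called at the stricter peak threshold, 696 and 27 when peaks had to cover 50% of a region, and 511 and 14 when every region was tested. Leaving out the ATF6, CEBPB, NFIL3 or XBP1 knockout gave 610, 668, 653 and 760 gained regions, while 1435 were gained without the ATF4 and 1137 without the CHOP knockout.

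Each knockout was then compared with the wild type of its own SET at gained regions chosen from the other SETs. In ATF4 knockout cells the gained regions were nearly empty, with a tunicamycin peak at 8.40% ± 2.11 (SD, n = 2) of 2244 regions against 85.2% ± 0.725 (SD, n = 2) in wild type. CHOP knockout cells had a peak at 41.7% ± 1.36 (SD, n = 2) of 2342 regions against 78.2% ± 4.56 (SD, n = 2). CEBPB knockout cells had 57.7% ± 0.220 of 2249 regions against 87.7% ± 1.54, XBP1 knockout cells 58.0% ± 4.38 of 2244 against 85.2% ± 0.725, and ATF6 knockout cells 68.3% ± 0.819 of 2244 against 85.2% ± 0.725 (SD, n = 2 each). NFIL3 knockout cells had 90.5% ± 1.21 of 2215 regions against 92.4% ± 0.543 (SD, n = 2 each), a difference below the pooled replicate SD of 2.27 points. In DMSO the mean shares were 1.89% to 8.60% in every genotype.

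**Figure D1:**
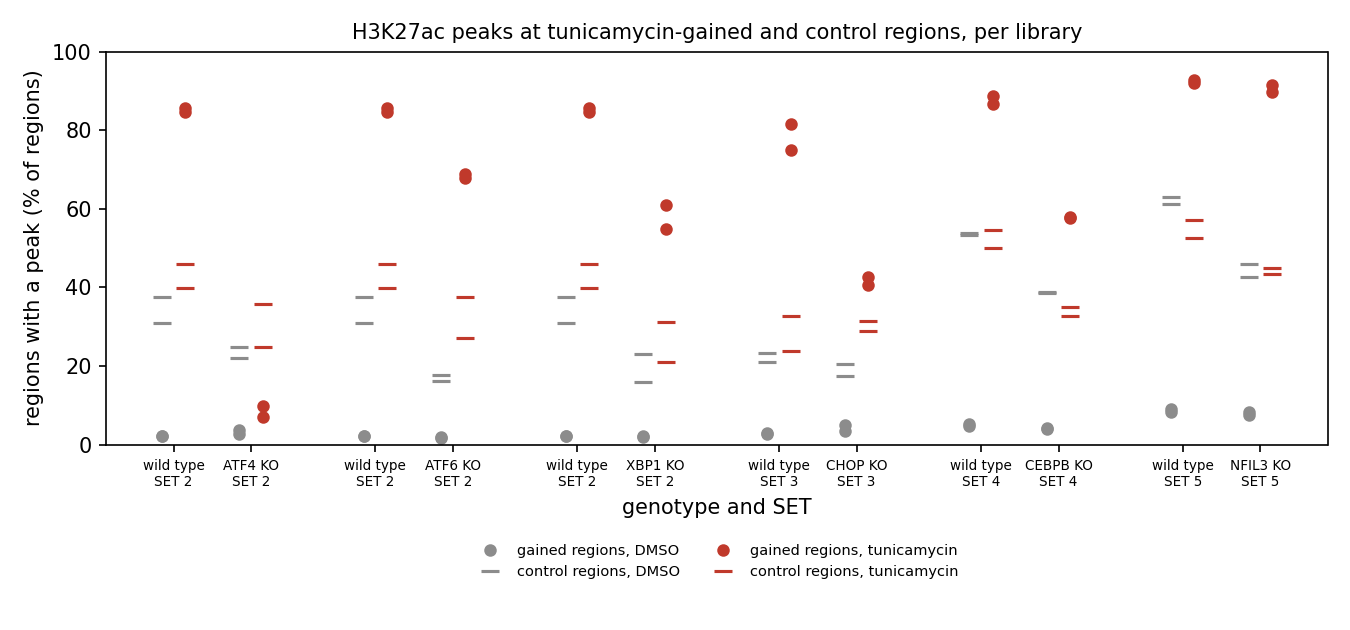
Share of regions with an H3K27ac peak (y axis, %) in each library, by genotype and SET (x axis), for gained regions (dots) and matched control regions (dashes) in DMSO (grey) and tunicamycin (red); the wild type of SET 2 is drawn 3 times because 3 knockouts share it. The ATF4 knockout tunicamycin libraries sit at a mean of 8.40%, and the wild-type ones of the same SET at 85.2%.

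Control regions also differed from wild type, by -12.8 points in ATF4, -10.6 in ATF6, -16.9 in XBP1, -18.5 in CEBPB, -10.6 in NFIL3 and 1.79 in CHOP knockout cells. The knockout difference at gained regions less that at control regions was -64.0 points for ATF4, -38.4 for CHOP, -11.5 for CEBPB, -10.3 for XBP1, -6.29 for ATF6 and 8.75 for NFIL3. In points, the control difference was 62.7% of the gained difference for ATF6, 62.1% for XBP1 and 61.7% for CEBPB, against 16.6% for ATF4. Control shares of wild-type tunicamycin cells started lower, at 43.0% in SET 2 and 52.3% in SET 4, against 85.2% and 87.7% at gained regions. Points therefore understate the fall at control regions relative to its start. From these values, lower library sensitivity cannot be told apart from a knockout effect for ATF6, XBP1 and CEBPB. In this measure the 6 knockouts together differed from the wild type of their SETs (permutation of genotypes within SETs, 20 libraries, p = 0.0366), while each single comparison of 2 against 2 libraries gave an exact two-sided p no lower than 0.333. That global p was 0.0701 at the stricter peak threshold. Without control regions subtracted, the difference was -1.87 points for NFIL3, and its sign changed at that threshold. In the same uncorrected measure ATF6 had -16.9 and CEBPB -30.0 points. At gained regions chosen from the other knockouts these became -4.67 for ATF6 and -8.46 for CEBPB.

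The next comparison asked whether the change was larger where the missing factor had a peak in wild-type cells. At 1227 gained regions with a CHOP peak the share was 88.1% ± 3.46 in wild type and 30.8% ± 0.634 in CHOP knockout cells (SD, n = 2 each), and at 826 regions without it 64.2% ± 5.74 and 54.9% ± 2.31. At 1632 regions with an ATF4 peak the share was 91.0% ± 0.303 in wild type and 4.29% ± 0.780 in ATF4 knockout cells, and at 449 regions without it 68.2% ± 1.57 and 22.7% ± 7.24. Few gained regions had an XBP1 or ATF6 peak. At the 50 with XBP1 the share was 92.0% ± 2.83 in wild type and 30.0% ± 8.49 in XBP1 knockout cells, and at the 43 with ATF6 it was 87.2% ± 1.64 in wild type and 39.5% in both ATF6 knockout libraries. The wild-type minus knockout difference with the factor peak exceeded that without it by 47.9 points for CHOP, 41.2 for ATF4, 35.7 for XBP1 and 31.6 for ATF6. For CEBPB the differences were 29.2 points at 941 regions with and 28.6 at 1041 without a CEBPB peak, an excess of 0.545 points that changed sign under the stricter factor threshold. For NFIL3 the excess was -3.16 points. These values were not tested, since each group has 2 libraries and regions are not replicates.

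**Figure D2:**
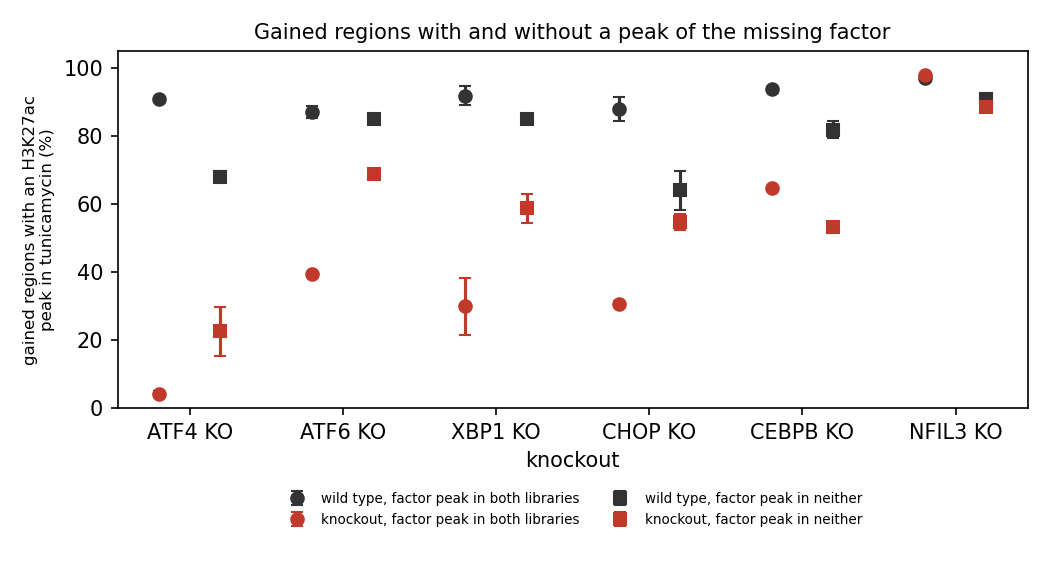
Mean share of gained regions with an H3K27ac peak in tunicamycin (y axis, %; error bars are SD of 2 libraries) for each knockout (x axis) in wild type (black) and knockout (red), at regions with a peak of the missing factor in both wild-type libraries (circles) or in neither (squares). In CHOP knockout cells the share at regions with a CHOP peak was 30.8%, and at regions without it 54.9%.

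Occupancy of the wild-type regions by the 6 factors was compared between gained regions and the 8437 other testable ones. ATF4 had a peak at 1933 of 2840 gained regions (68.1%) and at 397 others (4.71%), an odds ratio of 43.1 (95% interval 37.9 to 49.2). CHOP had a peak at 49.7% of gained and 2.83% of other regions (odds ratio 33.9, 29.2 to 39.5), and CEBPB at 37.4% and 2.55% (odds ratio 22.8, 19.5 to 26.8). For these 3 factors the adjusted p of Fisher's exact test was below the range of double precision. Lower odds ratios were found for XBP1 at 4.55 (3.10 to 6.71, exact test, adjusted p = 6.1e-16) and NFIL3 at 3.56 (3.03 to 4.2, exact test, adjusted p = 1.5e-52). ATF6 had a peak at 2.22% of gained and 1.47% of other regions (odds ratio 1.52, 1.10 to 2.08, exact test, adjusted p = 0.00837), a call that ended when a peak in 1 of the ATF6 libraries was enough (odds ratio 1.15, exact test, adjusted p = 0.286). These odds ratios hold against regions that vary between libraries. Against the 24593 other H3K27ac regions of wild-type tunicamycin cells, a background chosen after the data were seen, the direction turned for ATF6, present at 15.3% of them (odds ratio 0.125, 0.0958 to 0.161), and for XBP1, present at 9.92% (odds ratio 0.236, 0.184 to 0.30). Against the same background the odds ratio was 13.6 for ATF4, 9.88 for CHOP, 6.47 for CEBPB and 1.23 for NFIL3 (1.09 to 1.39, exact test, adjusted p = 0.000808). Regions were not matched for width against either background. All of ATF4, CHOP and CEBPB together were present at 922 gained regions (32.5%) and 82 others (0.972%). No peak of the 6 factors was present at 668 gained regions (23.5%). Of the 260 lost regions, 2 had an ATF4 peak, 1 a CEBPB peak, 9 an NFIL3 peak, 2 an ATF6 peak, and 0 a CHOP or XBP1 peak. In DMSO, 2.46% of the gained regions already had an ATF4 peak, 3.66% a CEBPB peak and 4.30% an NFIL3 peak.

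**Figure D3:**
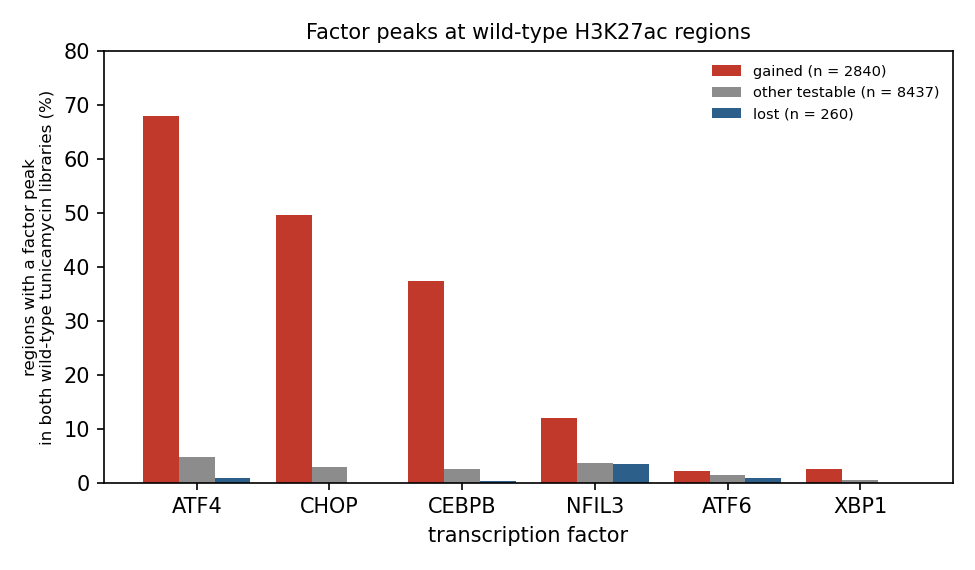
Share of wild-type H3K27ac regions with a factor peak in both wild-type tunicamycin libraries (y axis, %) for each of the 6 factors (x axis), at gained regions (red), other testable regions including the lost ones (grey) and lost regions (blue). ATF4 has the highest bar at gained regions, 68.1%, and the lost regions stay at or below 3.46%.

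ATF4 binding was compared between treatments over 6 genotypes. Tunicamycin raised ATF4 peak numbers in all of them, from 551 ± 130 to 15491 ± 245 (SD, n = 2 each) in wild type, 28.5-fold by geometric means, and between 8.29-fold and 17.2-fold in the knockouts. Over the 24 libraries the log2 ratio was 3.74 (permutation test, two-sided, n = 12 per treatment, p = 2e-05, the smallest the permutations can give). Of 18657 testable ATF4 regions, 18540 were gained and 1 was lost (Fisher's exact test, n = 12). The DMSO lists held 459 to 2730 peaks and the tunicamycin lists 13065 to 31891. A gain at nearly all testable regions therefore largely follows from the difference in peak number. The treatment test on ATF4 lists of equal length was not run. The 10 leading gained regions, with a peak in 12 of 12 tunicamycin and 0 of 12 DMSO libraries (Fisher's exact p = 7.4e-07, adjusted p = 6.3e-06), lay on chromosome 20 at 509097 to 511001, chromosome 2 at 238374066 to 238375261, chromosome 18 at 12606054 to 12607832, chromosome 10 at 73025404 to 73026984, chromosome 11 at 13283232 to 13284616, chromosome 12 at 52166561 to 52167676, chromosome 8 at 124070065 to 124071322, chromosome 19 at 39928794 to 39929922, chromosome 14 at 96357823 to 96359231 and chromosome 1 at 182584883 to 182587797. Each of the 10 also had a CHOP peak in wild-type tunicamycin cells. The lost region lay on chromosome 1 at 45186859 to 45187699, with a peak in 1 of 12 tunicamycin and 8 of 12 DMSO libraries (Fisher's exact p = 0.00942, adjusted p = 0.0129), and it carried an NFIL3 peak.

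ATF4 peak numbers were more alike within than between genotypes in DMSO (exact permutation test over pairings, one-sided, p = 0.0141, adjusted p = 0.0283) and in tunicamycin (exact permutation test, p = 0.0417, adjusted p = 0.0417). Depth is unknown, so the test cannot separate an effect of genotype from a difference in library sensitivity between the groups. In tunicamycin the NFIL3 knockout had 30913 ± 1383 peaks (SD, n = 2), 2.0 times the wild-type number, and the other knockouts 1.06 to 1.31 times that number. In DMSO the knockouts had 2.16 to 4.46 times the 551 peaks of wild type. Of 11154 wild-type tunicamycin ATF4 sites, 98.4% ± 0.254 (SD, n = 2) had a peak in NFIL3 knockout cells, 86.0% ± 5.55 in CEBPB, 85.9% ± 7.70 in ATF6, 84.2% ± 0.856 in XBP1 and 76.6% ± 0.114 in CHOP knockout cells. These sites had a peak in both wild-type libraries, which favours sites found again. Of all peaks of a single wild-type library, 71.5% and 73.0% overlapped a peak of the other. With all sites of a single wild-type library in place of the shared ones, the mean share with a peak was 70.4% and 72.4% in ATF6, 69.0% and 70.9% in XBP1, 67.8% and 69.7% in CHOP, 72.4% and 74.0% in CEBPB and 89.8% and 91.9% in NFIL3 knockout cells. With the lists trimmed to equal length, the shares were 70.7% in CHOP and 89.9% in NFIL3 knockout cells.

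CHOP binding was compared between wild-type and ATF4 knockout cells. In wild type, CHOP peaks numbered 8 in each DMSO library and 6124 and 8812 in tunicamycin. In ATF4 knockout cells they numbered 2 in each DMSO library and 27 and 23 in tunicamycin. Of 5509 wild-type tunicamycin CHOP sites, 26 (0.472%, exact 95% interval 0.309% to 0.691%) and 22 (0.399%, 0.250% to 0.604%) had a peak in the ATF4 knockout libraries. The intervals cover counting error over sites only. The peak numbers skip 65.8% and 70.1% in the ATF4 knockout tunicamycin lists, against 2.16% and 2.14% in the wild-type tunicamycin lists. The knockout counts and shares may therefore leave out called peaks. The highest running numbers were 79 and 77 in the knockout lists, against 6259 and 9005 in the wild-type ones. Peaks skipped below those numbers are too few to make up the difference in peak number. Without wild-type replicate 1 the mean share was 0.278%, against 0.436% with both. With 2 libraries per group no exact test can go below p = 0.333.

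The 6 factors fell into classes by their response in wild-type cells. XBP1, a factor activated by IRE1-dependent splicing, had 142 ± 12 peaks in DMSO and 4009 ± 553 in tunicamycin (SD, n = 2 each), and NFIL3, a basic leucine zipper factor, had 5663 ± 832 and 16735 ± 1792. CEBPB, another basic leucine zipper factor, had 7519 ± 4263 peaks in DMSO and 8118 ± 237 in tunicamycin, and ATF6, a membrane-bound factor released by cleavage under ER stress, had 7729 ± 1443 and 6551 ± 1298, differences within the spread between replicates. The exact two-sided permutation p was 0.333 for ATF4, CHOP, NFIL3 and XBP1, 1.00 for CEBPB and 0.667 for ATF6, and no factor could go below 0.333. Without DMSO replicate 2, which had 4504 peaks against 10533 in replicate 1, the log2 ratio of CEBPB turned from 0.24 to -0.38. Sites with a peak in both tunicamycin and neither DMSO library made up 99.9% of the 5509 CHOP sites, 93.7% of the 11154 ATF4 sites, 93.6% of the 2668 XBP1 sites, 45% of the 10107 NFIL3 sites, 37.0% of the 5903 CEBPB sites and 18.5% of the 4237 ATF6 sites. The opposite pattern, a peak in both DMSO and neither tunicamycin library, was seen at 870 ATF6 sites, against 785 tunicamycin-only ones. It was seen at 543 CEBPB and 44 NFIL3 sites, and at 0 sites of CHOP, ATF4 and XBP1. CEBPB sites differed by class. Of the 2184 tunicamycin-only CEBPB sites 90.8% had an ATF4 peak, against 18.2% of the 2761 sites present in all 4 libraries (odds ratio 44, 95% interval 36.9 to 52.7). NFIL3 showed the reverse order, 9.64% of 4552 tunicamycin-only sites against 19.6% of 2978 sites in all 4 libraries (odds ratio 0.439, 0.383 to 0.502, exact test over sites, adjusted p = 1.4e-33). The odds ratio was 1.74 for ATF6 (1.31 to 2.29, exact test, adjusted p = 0.00018) and 2.11 for XBP1 (1.09 to 4.57, exact test, adjusted p = 0.0246), and only 3 CHOP sites were present in all 4 libraries.

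**Figure D4:**
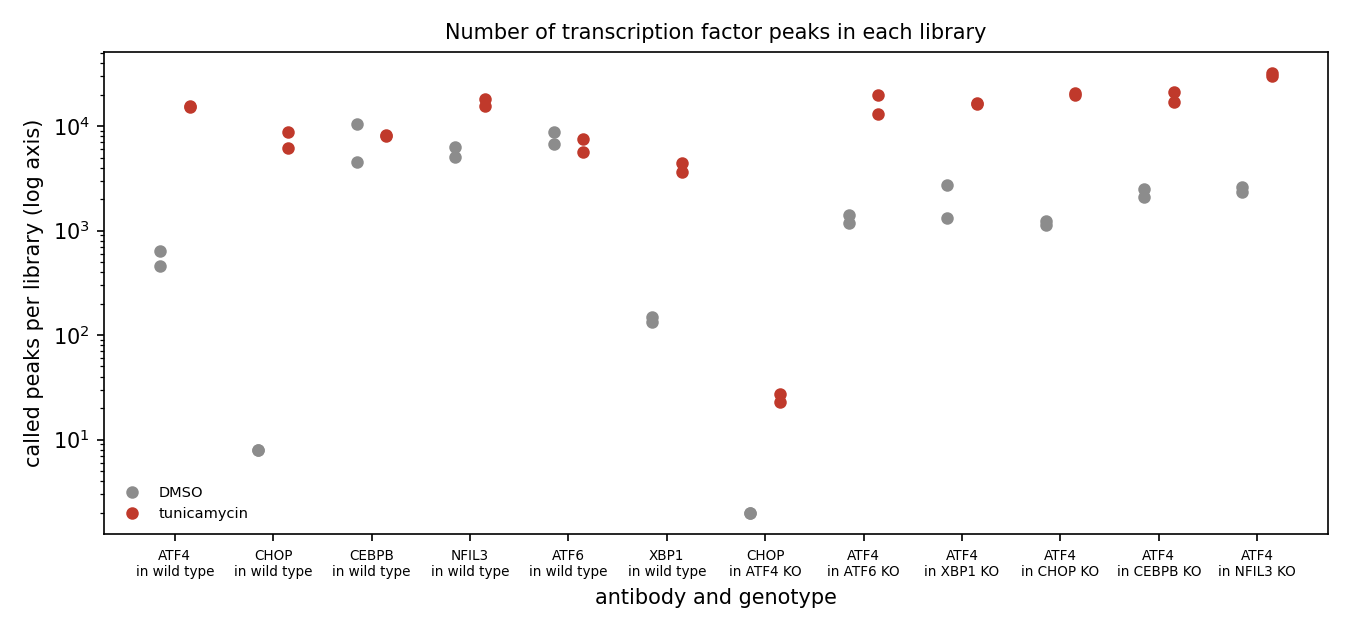
Called peaks per library (y axis, log scale) for each antibody and genotype (x axis) in DMSO (grey) and tunicamycin (red), with 1 point per library. CHOP has 6124 and 8812 peaks in wild-type tunicamycin libraries and 27 and 23 in ATF4 knockout tunicamycin libraries.

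A pair of the leading tunicamycin-only sites overlapped between factors. CHOP and CEBPB shared a site on chromosome 20, at 361203 to 362062 for CHOP and 361256 to 362073 for CEBPB, and ATF6 and XBP1 shared a site on chromosome 3, at 5064476 to 5065669 for ATF6 and 5064076 to 5065833 for XBP1. The other leading CHOP sites lay on chromosome 9 at 128005244 to 128006122, chromosome 3 at 111623150 to 111624238, chromosome 19 at 45091465 to 45092180 and chromosome 17 at 54993048 to 54993903. Those of CEBPB lay on chromosome 20 at 382397 to 383096, chromosome 3 at 12235823 to 12236681, chromosome 19 at 2059383 to 2060042 and chromosome 1 at 109757236 to 109758052. The ATF4 sites lay on chromosome 17 at 54864078 to 54865369, chromosome 10 at 43875989 to 43877011, 104215432 to 104216185 and 103698068 to 103699499, and chromosome 3 at 190103878 to 190104733. For NFIL3 they lay on chromosome 3 at 66448142 to 66448629, chromosome 11 at 15074733 to 15075214, chromosome 5 at 77995196 to 77995648, chromosome 2 at 137005974 to 137006263 and chromosome 10 at 95196682 to 95197150. The chromosome 11 site lies inside a leading gained H3K27ac region, at 15073135 to 15080196. Other ATF6 sites lay on chromosome 20 at 44849195 to 44850059, chromosome 3 at 16142615 to 16143392, chromosome 2 at 28819536 to 28820266 and chromosome 7 at 108209857 to 108211279, and other XBP1 sites on chromosome 22 at 21995648 to 21997285, chromosome 14 at 100842078 to 100843515, chromosome 9 at 100818448 to 100819490 and chromosome 8 at 71519193 to 71520827.

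Co-occurrence of the factors was measured over 27433 H3K27ac regions of wild-type tunicamycin cells. Factor peaks anywhere in the same region counted as meeting, and single H3K27ac peaks reached up to 137184 bp. Region width was not controlled for, and a wide region can hold peaks of several factors at separate sites. ATF4, CHOP and CEBPB met most often, with odds ratios of 49.3 for ATF4 and CHOP (3046 regions with both, 699 for independent placing), 39.7 for CHOP and CEBPB (2232 against 418) and 27.6 for ATF4 and CEBPB (2457 against 601). ATF6 and XBP1 formed another pair, with an odds ratio of 13.4 (1466 against 351, 95% interval 12.2 to 14.6). NFIL3 met CEBPB, ATF4 and CHOP with odds ratios of 6.16, 5.15 and 4.36. XBP1 met NFIL3, CEBPB, CHOP and ATF4 with odds ratios of 2.44, 2.0, 1.72 and 1.59, and NFIL3 met ATF6 with 1.27. ATF6 met ATF4 and CHOP less often than independent placing gives, with odds ratios of 0.757 (0.689 to 0.832, exact test, adjusted p = 2.6e-09) and 0.703 (0.627 to 0.786, exact test, adjusted p = 1.7e-10). CEBPB and ATF6 had an odds ratio of 0.986 (Fisher's exact test, adjusted p = 0.827), the pair among the 15 that did not pass, and its direction changed with the settings. Regions are not independent replicates.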

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

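The test of library sensitivity and the splits of the wild-type H3K27ac libraries were chosen after the result was seen. The share of gained H3K27ac regions with a peak in tunicamycin, less that of control regions, differed between the 6 knockouts and the wild type of their SETs (permutation within SETs, p = 0.0366), and at the stricter peak threshold the permutation p was 0.0701. The largest of the 6 differences was that of the ATF4 knockout. It weighs most in the sum of squares tested, so the p-value says little about the smaller differences. Among the 10 wild-type H3K27ac libraries of each treatment, no single library lay apart in peak number, covered length or median width by Dixon's ratio, which cannot see a pair of libraries that stand apart together. The tunicamycin libraries of SET 1 covered 66.0 and 64.6 Mb, against 49.1 to 57.7 Mb in the others, and its DMSO libraries had 41315 and 40579 peaks, against at most 36816.

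The near absence of gained regions in ATF4 knockout cells was weighed against 3 technical explanations. Lower sensitivity of the knockout libraries would empty control regions as well, and their fall in points was 16.6% of the fall at gained regions. The control share was 30.2% ± 7.72 in ATF4 knockout cells and 43.0% ± 4.36 in wild type (SD, n = 2 each). At gained regions the shares were 8.40% and 85.2%. A chromosome copy lost in the clone would leave the other chromosomes near the wild type, and the highest ATF4 knockout share on any of the 23 chromosomes was 12.5%, against 79.3% or more in wild type. Cells that never received tunicamycin would stay at the DMSO level everywhere, and at the 50 gained regions with an XBP1 peak the ATF4 knockout share was 33.0 points higher in tunicamycin than in DMSO, at 41.0% ± 12.7 against 8% ± 2.83 (SD, n = 2). These values argue against each of them as the whole cause, and a requirement for ATF4 may be the reason as a hypothesis, with a difference between cell clones untested.

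The region tests were set against other splits of the same libraries, 100 splits with the real one included. For wild-type H3K27ac the real split called 3100 regions by Fisher's exact test and the highest other split 0, so 1 of 100 splits, the real one, reached its value. With 100 splits no share below 1 of 100 can be reached, so chance is bounded only at that level. The 49 drawn splits that part every pair of the same SET and number had 20 to 1721 regions at an unadjusted p under 0.05, and the 50 drawn at random had 19 to 1626, against 4163 in the real split. For the knockouts the real split called 1495 regions and the highest other 0 (1 of 100), with 26 to 1014 regions at an unadjusted p under 0.05 in splits that part every pair and 47 to 1894 in those drawn at random, against 3201. For ATF4 the real split called 18541 regions and the highest other 0 (1 of 100), with 3 to 1587 at an unadjusted p under 0.05 in the 99 others.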

How the results depend on the processing

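Alternatives were tried for 56 values, and 379 of 491 alternative values kept the direction and the side of the threshold or, without a test, stayed within the replicate spread or the range set beforehand for counts, while 10 reversed. A background of all H3K27ac regions in tunicamycin was the 1 alternative added after the data were seen. Gene lists were not run, since the gene table belongs to another build. Depth is unknown and limits what a missing peak means. The cause was not tested for the changes listed here except where the setting tests other regions or fewer libraries.

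Wild-type H3K27ac regions, 2840 gained and 260 lost, came to 1820 and 107 at the stricter threshold and to 1867 and 70 when every region was tested, which spreads the adjustment over more regions. Lost regions numbered 149 with merging within 500 bp, 497 when stratified by SET, and 164, 167, 124 and 116 without SET 1, 2, 4 and 5, which leaves fewer libraries. With lists of equal length 1953 were gained and 349 lost. Leaving out single libraries gave 287 to 399 lost regions, with 399 and 395 without DMSO replicate 1 or 2 of SET 3.

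Knockout H3K27ac regions, 1420 gained and 75 lost, came to 842 and 24 at the stricter threshold, 696 and 27 when peaks had to cover 50% of the region, 511 and 14 when every region was tested, 1040 and 107 with lists of equal length, and 2214 and 167 when stratified by genotype. Lost regions numbered 46 with merging within 500 bp. With the replicate block 2322 were gained and 209 lost. Without the ATF6, CEBPB, NFIL3 and XBP1 knockouts 610, 668, 653 and 760 were gained and 32, 27, 31 and 29 lost.

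The 1 lost ATF4 region became 0 when peaks had to cover 50% of the region and without the CHOP, NFIL3 or XBP1 knockout. Leaving out single libraries gave 1 to 2, with 2 without either DMSO library of wild type or of the ATF6, XBP1 or CHOP knockout. In the ATF4 lists the deviations of same-numbered libraries correlated at -0.145 to 0.0428, so the number does not pair them, and the replicate block called 15967 gained regions against 18540. In wild-type H3K27ac the block called 3024 gained and 350 lost regions, among them all 2840 and 260. It turned no other direction and moved no other test across its threshold. It gave a p of 0.00586 for the H3K27ac peak number by exact sign flips.

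The log2 ratio of the wild-type H3K27ac peak number was 0.12 to 0.17 over single libraries left out. That of CEBPB turned to -0.083 by covered length and ranged from -0.38 to 0.85 over single libraries, the lowest without DMSO replicate 2.

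The ATF4 knockout difference of -76.8 points was -66.9 with 50% cover. For ATF6 (-16.9) it was -21.6 at the stricter threshold, -19.3 with 50% cover, -21.2 with regions from all SETs and -4.67 with regions from the knockouts. XBP1 (-27.2) gave -34.8, -31.6, -31.9 and -24.1 in the same order, -23.1 with equal list length and -30.3 to -24.1 over single libraries. CHOP (-36.6) gave -29.2, -26.1, -39.2 and -31.1, -31.4 with equal length and -39.8 to -33.4 over single libraries. CEBPB (-30.0) gave -38.1 with 50% cover, -34.1 with all SETs, -8.46 with the knockouts and -24.5 with equal length. NFIL3 (-1.87) turned to 0.365 at the stricter threshold and 0.915 with equal length, and was -5.44 with 50% cover and -5.39 with all SETs. The global p was 0.0701 at the stricter threshold.

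The excess of the wild-type minus knockout difference at regions with the missing factor was 35.1 for ATF6 and 41.6 for XBP1 at the stricter factor threshold, 22.6 for XBP1 and 42.1 for CHOP when a peak in 1 library was enough, and 35.2 for ATF6 by summit. For CEBPB it turned to -1.34 at the stricter threshold and -0.514 by summit. The ATF6 odds ratio at gained regions was 1.15 (exact test, adjusted p = 0.286) when a peak in 1 library was enough. Against all other H3K27ac regions in tunicamycin it turned to 0.125, and that of XBP1 to 0.236. The CEBPB and ATF6 pair had odds ratios of 1.07 at the stricter threshold, 1.06 by summit and 0.847 with a peak in 1 library (exact test, adjusted p = 3.4e-05).

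ATF4 sites kept, at the stricter wild-type threshold, were 92.3% in ATF6, 91.4% in XBP1 and 91.4% in CEBPB knockout cells, and with equal length 70.7% in CHOP and 89.9% in NFIL3 knockout cells. Over single libraries left out they ranged from 70.4% to 91.3% in ATF6, 69.0% to 84.8% in XBP1, 67.8% to 76.6% in CHOP, 72.4% to 89.9% in CEBPB and 89.8% to 98.6% in NFIL3 knockout cells. CHOP sites kept without ATF4 were 0.496% at the stricter wild-type threshold and 0.278% to 0.472% over single libraries, the lowest without wild-type replicate 1.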

Other observations

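The comparisons of ATF4 sites by CHOP peak, of ATF4 sites in DMSO, and of regions absent in several knockouts were chosen after the main results were seen, and the other tests were set before their values were known. ATF4 sites with and without a CHOP peak differed in CHOP knockout cells. In CHOP knockout cells 58.4% ± 0.259 (SD, n = 2) of the 4098 wild-type ATF4 sites with a CHOP peak kept an ATF4 peak, against 90.7% ± 0.0985 of the 5741 sites without one, although sites with CHOP were the stronger ones in wild type (median within-list percentile 79.3 against 49.0). The order was the opposite in XBP1 knockout cells, at 94.3% ± 0.949 with CHOP and 75.9% ± 0.702 without, and in ATF6 knockout cells, at 91.5% ± 4.47 and 81.5% ± 10.0. In CEBPB knockout cells the shares, 87.8% ± 4.00 and 85.5% ± 6.68, differed by less than the replicate spread, and in NFIL3 knockout cells they were 99.5% ± 0.0690 and 97.4% ± 0.345. The difference between knockouts was not tested. Nearly all ATF4 sites found in DMSO were also tunicamycin sites of wild type, from 98.4% in CEBPB knockout to 100% in ATF6 knockout cells, although the knockouts had 828 to 1681 such DMSO sites and wild type 383.

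Gained H3K27ac regions absent from a knockout were compared with those absent from another knockout of a different SET. Of 798 gained regions absent in both CHOP knockout libraries, 94.1% were absent in both ATF4 knockout libraries (751, where 661 would be shared by independent lists, odds ratio 5.75, 95% interval 4.13 to 8.17). CHOP and CEBPB knockout cells shared 299 against 180 (odds ratio 4.71, 3.70 to 6.02), and ATF6 and CEBPB knockout cells 157 against 68.5 (odds ratio 5.39, 4.10 to 7.11). XBP1 and CHOP knockout cells shared 182 against 176, with an odds ratio of 1.09 (0.863 to 1.37, Fisher's exact test, adjusted p = 0.489), and ATF4 and NFIL3 knockout cells had 1.41 (Fisher's exact test, adjusted p = 0.412). The remaining pairs had odds ratios of 1.75 to 8.11, the highest for CEBPB and NFIL3. The gained share of NFIL3 knockout cells differed from wild type by -1.87 points, less than the replicate SD pooled over genotypes of 2.27, so such overlap does not by itself show a shared effect of the knockouts.

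The gained regions that ATF4 knockout cells kept may depend on the ATF6 and XBP1 arms of the ER stress response, as a hypothesis. Of 112 gained regions with a peak in both ATF4 knockout tunicamycin libraries, 13.4% had an XBP1 peak, against 1.21% of the 1979 with a peak in neither (odds ratio 12.6, 95% interval 5.92 to 25.9, Fisher's exact test, adjusted p = 5.8e-10). For ATF6 the shares were 8.93% and 1.11% (odds ratio 8.70, 3.58 to 19.8, Fisher's exact test, adjusted p = 3.1e-06). An ATF4 peak was present at 35.7% of the kept and 77.4% of the absent regions. Most of the kept regions had neither an XBP1 nor an ATF6 peak. At the gained regions with an XBP1 peak the tunicamycin share was 92.0% in wild type and 41.0% in ATF4 knockout cells. Kept regions were not screened for a peak in DMSO. The ATF4 knockout DMSO libraries had one at 3.61% and 2.67% of all gained regions, against 9.89% and 6.91% in tunicamycin. At the other H3K27ac regions of wild-type tunicamycin cells, 9.92% had an XBP1 peak and 15.3% an ATF6 peak, so the ATF6 share of the kept regions was below that of marked regions in general.

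NFIL3 knockout cells had 6927 ATF4 sites found in both of their tunicamycin libraries and in neither wild-type one. Relief from NFIL3 occupying those sites in wild type was tested as a hypothesis, and 5.95% of them had a wild-type NFIL3 peak, inside the range of 5.28% to 8.32% at the extra sites of the other knockouts, which argues against it. Higher library sensitivity cannot be told apart from a wider ATF4 spread, since the median within-list percentile of the extra sites was 37.1, between the bounds set beforehand for weak and for ordinary sites.

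Gained regions did not lie closer together than draws of testable regions, which could include gained ones. Another gained region lay within 100 kb of 37.5% of them, and 1000 draws of as many testable regions per chromosome gave 36.5% to 42.8%. The densest group, chosen after its values were seen, held 9 gained regions on chromosome 10 between 105238743 and 105316257.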
